A study of Mus musculus with 8 samples.

How the data were processed

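Hearts of male mice were profiled by paired-end sequencing of total RNA, per the labels' protocols. The labels name 4 WT and 4 ARE-/- hearts of strain C57B6/J, age matched at 20 to 25 weeks. Each library was taken as a separate mouse, since the study's design counts 4 animals in each group. The p-values of single genes and of library measures rest on the spread between these libraries. They would be too small if the 3 libraries that lay close together in each group were repeats of a single RNA or pool. The counts leave this open. The labels do not spell out ARE. It was read here as the AU-rich element in the 3′ untranslated region (3′UTR) of Ifng, an element known to shorten the life of the transcript of interferon gamma (IFN-γ). Groups came from the library titles, and columns were matched to libraries by the code in each title.

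The submitters' processing notes name the aligner STAR, the test DESeq2 and the mouse build mm10, without versions. The read counter, its use of strand and the annotation release are not given in the sources used here. Genes that overlap another gene or have a near-identical copy are therefore uncertain, and a gene and its antisense partner cannot be told apart. The deposited gene table holds whole read counts per gene and library, per the file headers. It also holds FPKM, fragment counts scaled to gene length and library depth, that the authors computed per library. Dividing counts by deposited FPKM and gene length gave the same library total for every gene of a library, from 13416171 to 19432098 reads. The deposited normalised signal of each group is the authors' mean of counts divided by size factors, and solving these means for the counts gave each library's size factor. The log2 fold changes and the p-values, raw and adjusted, are those of the authors in the deposited table. In 1474 genes the authors' log2 fold change lay closer to 0 by more than 0.1 than the log2 ratio of the group means of normalised counts. That ratio is another measure than the log2 differences reported below. A second deposited table holds p-values of Gene Ontology (GO) terms by the authors. Its tool is not given in the sources used here, and a spreadsheet had turned some of its ratio cells into dates, so the column of gene counts was used.

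The gene table lists only genes with an adjusted p under 0.05 by the authors, 4820 of the 19606 genes that the adjustment itself implies were tested. Genes outside that list were not analysed here, so no count of changed genes was made anew and a gene that is not listed has no known direction. The authors' calls were taken as the result. Normalised counts are counts divided by the authors' size factors. Log2 differences are the mean of log2(normalised count + 0.5) in ARE-/- minus that in WT, with the SE from 4 mice per group, and means of normalised counts are given with the SD. The offset of 0.5 draws the differences of low genes towards 0.

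A total of 40 gene lists were fixed before the data were examined. For each list with at least 5 listed members, Fisher's exact test (two-sided) compared risen and fallen genes between its members and all other listed genes, with Benjamini-Hochberg adjustment over the 35 such lists. This test asks whether a list leans one way more than the other listed genes, not whether it holds more changed genes than unlisted ones. It counts genes as independent and does not measure the spread between libraries. Its p-values are too small where members of a list move together. Genes were named by a rule fixed at the same time. It takes Ifng, then the 8 largest rises and the 8 largest falls among protein-coding genes with a mean above the median of the listed genes and with no overlap between groups. It then takes up to 4 members of each list by adjusted p, and all members of lists with few listed genes, 149 genes in all. Members singled out because they went against their list were chosen after their values were seen. Some single genes are not reported here. Library measures were compared by exact two-sided permutation tests, whose smallest possible p with 4 against 4 is 0.0286.

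Refits on the listed genes served only as alternatives, because the genes had been selected on the same libraries. They used edgeR 4.0.16 (quasi-likelihood) with limma 3.58.1 in R 4.3.3, or DESeq2 1.42.0, with p-values adjusted as if all 19606 genes had been tested. Alternatives set beforehand were a stricter adjusted p, a minimum fold change, minimum levels, protein-coding genes alone, trimmed mean scaling (TMM), a replicate block and leaving out each library in turn. Alternatives added after seeing the data were scaling by library totals, leaving out both libraries that stood apart, summing the 3 close libraries of each group to 1 replicate, and per-library offsets that remove the trend with the GC content of transcripts. Those offsets were estimated on the selected genes themselves and can also remove real differences. Transcript GC content came from the GENCODE mouse annotation of the same build, in which 4790 of the 4820 gene identifiers were found. Tables were handled in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and SciPy 1.17.1, and plots were drawn with matplotlib 3.10.9.

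The edgeR step was tested on simulated counts for the 4820 genes with 200 changed genes. It recovered 59% of 2-fold and 89% of 4-fold changes, all with the right sign, with 3.27% false calls. P-values were adjusted there over the 4820 genes, less strictly than over the 19606 of the refits. The simulated libraries were independent, with none that stood apart and no GC trend. These rates may therefore not hold for the refits. The list test was checked on 200 simulated lists of 20 members. It called 4% of lists with no effect and 97% of lists in which 90% of members rose. Directions were drawn for each gene independently, so these rates do not hold for lists whose members move together.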

Results

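The study compared hearts of 4 WT and 4 ARE-/- male mice by RNA sequencing. Its title names IFN-γ, androgens and mitochondrial function in myocytes as the subject, and the comparison asks how cardiac transcripts differ when the element that limits Ifng transcripts is missing. Library totals were 14321679, 14566851, 17129012 and 16023978 reads in WT and 15674834, 13416171, 17937623 and 19432098 reads in ARE-/-, in order of replicate number, and did not differ beyond the spread (exact permutation p = 0.514). The listed genes took 59.1% ± 1.63 of the reads in WT and 52.0% ± 2.48 in ARE-/- (SD, n = 4 each, exact permutation p = 0.0286).

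Ifng itself, which encodes IFN-γ, was close to undetected in WT hearts and abundant enough to count in every ARE-/- heart. The gene (ENSMUSG00000055170) lies on the forward strand of chromosome 10, from 118441047 to 118445892 in mm10. The annotation places its 3′UTR, the part read here as targeted, at 118445259 to 118445892, 634 bases long, and the bounds of the deletion are not given in the sources used here. The WT libraries held 0, 3, 0 and 1 Ifng reads and the ARE-/- libraries 103, 37, 27 and 61. Normalised counts were 1.15 ± 1.69 in WT and 49.5 ± 25.4 in ARE-/- (SD, n = 4 each), a log2 difference of 5.34 ± 0.82 (SE), and each ARE-/- library lay above each WT library. Summed over libraries and set against library depth, the ARE-/- to WT ratio was 46.5, with an exact 95% interval of 17.9 to 172 that covers counting error only. The authors' deposited table gives a log2 fold change of 4.01 and an adjusted p of 3.1e-12 (DESeq2).

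Beyond Ifng, ARE-/- hearts carried far more transcript of interferon-induced, antigen-presenting and immune-cell genes, and less transcript of mitochondrial, contractile and red-cell genes. Interferon-inducible GTPases were among the highest rises of well-expressed genes. Gm12185 went from 16.1 ± 9.04 to 4846 ± 497 normalised counts (SD, n = 4 each), a log2 difference of 8.37 ± 0.44 (SE), and Gm4841 rose by 7.93 ± 0.29. Ubd, a ubiquitin-like modifier that marks proteins for the proteasome, rose by 8.25 ± 0.54. Other large rises among the protein-coding genes named by the rule were F830016B08Rik (7.22 ± 0.49), Apol9a (7.02 ± 0.55) and the transcription factor Batf2 (6.67 ± 0.47). The connexin Gjd3 (6.59 ± 0.74) and the GTPase Igtp (6.03 ± 0.18) were the last of them. Among protein-coding genes above the median level whose groups did not overlap, Lgals4, which encodes galectin 4, had the largest fall, at -3.53 ± 0.15, from 559.5 ± 73.0 to 48.0 ± 8.11 normalised counts. Falls of -2.69 ± 0.39 and -2.42 ± 0.36 were seen in the alpha-globin genes Hba-a2 and Hba-a1. The myosin Myh7b followed at -2.38 ± 0.32, with the mitochondrial iron importer Slc25a37 at -2.31 ± 0.42 and Cenpf at -2.10 ± 0.15. Btnl9 fell by -2.05 ± 0.12 and Rmnd1, a factor of mitochondrial translation, by -1.92 ± 0.18. Reads of the globin pair, of Apol9a and of the GTPases Gm4841 and F830016B08Rik may be shared with near-identical copies, so these single-gene values are uncertain.

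The authors' deposited table lists 4820 genes with an adjusted p under 0.05 by DESeq2, 24.6% of the genes tested, of which 2512 rose and 2308 fell. In 3929 of them (81.5%) the 4 ARE-/- values lay entirely to one side of the 4 WT values, a share that the selection of genes on these libraries itself raises, so the 2.86% that chance gives for unselected genes is no yardstick. At least 2-fold changes were seen in 1275 risen and 1178 fallen genes. The balance of rises and falls depended on scaling. Of the listed genes past the threshold, 52.1% rose with the authors' size factors, 42.1% in an edgeR refit with TMM and 70.7% with library totals, which shift the median of the listed genes by 0.20 on the log2 scale.

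Libraries of a group were not equally close to one another. ARE-/- replicate 1 stood apart from its group in 692 of the 2410 more highly expressed genes (28.7%), and WT replicate 3 in 205 (8.51%). The other 3 libraries of each group differed from one another by a biological coefficient of variation of 6.08% in WT and 5.88% in ARE-/-, against 14.01% and 25.2% with all 4 libraries. Leaving out both libraries left 4723 genes past the threshold of the edgeR refit. Summing the close libraries to 1 replicate left 297, of which 91.9% rose. The difference between genotypes also followed the GC content of transcripts, with a Spearman correlation across 2408 genes of 0.487, and 0.545 without both libraries that stood apart (genes are not independent replicates). Offsets that remove this trend, chosen after seeing the data and able to remove real differences too, left 2444 genes past the threshold of the edgeR refit, 57.4% of them risen. Counts with these GC offsets are given beside the fixed gene lists.

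Interferon-response genes rose almost without exception. Of 57 genes on the IFN-γ response list, 47 were listed and all 47 rose (Fisher's exact adjusted p = 2.8e-12), with a median log2 difference of 3.62. They included the GTPases Igtp and Iigp1 (4.89 ± 0.15), the nucleic acid sensor Zbp1 (5.57 ± 0.15) and Cd274, which encodes the checkpoint ligand PD-L1 (4.09 ± 0.10). The type I interferon list had 38 of 45 genes listed, 37 risen and 1, Isg20, fallen (adjusted p = 1.9e-08, Fisher's exact test), with Ifi27 (2.21 ± 0.03), Irf7 (3.65 ± 0.14), Usp18 (3.83 ± 0.15) and Ifit3 (3.83 ± 0.16) among the risen. With GC offsets 47 of 47 and 36 of 38 rose, and 1 type I gene fell. The highest median of the IFN-γ list was that of ARE-/- replicate 1, 4.10, against 3.56 to 3.64 in the other ARE-/- libraries. In the authors' deposited table the adjusted p of the 8 risen genes named here, which the naming rule took for their small p, ran from 6.9e-226 for Igtp to 6.2e-88 for Ifit3 (DESeq2).

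Genes that present antigen to T cells rose together. All 23 listed genes of the class I list of 26 rose (Fisher's exact adjusted p = 3.9e-06, median 3.13), among them H2-T22 (3.87 ± 0.10), H2-Q6 (4.06 ± 0.13), the immunoproteasome subunit Psmb9 (4.63 ± 0.17) and H2-T23 (4.32 ± 0.16). All 12 listed genes of the class II list of 13 rose too (Fisher's exact adjusted p = 0.00146, median 4.26). H2-DMb1 rose by 5.23 ± 0.16, H2-DMa by 4.72 ± 0.28, H2-Eb1 by 4.52 ± 0.25 and H2-Ab1 by 5.01 ± 0.35. H2-Ab1 counts went from 1243 ± 599 to 38241 ± 8598 (SD, n = 4 each). Members of the H2-Q and H2-T families resemble one another closely, so the split of reads between them is uncertain. With GC offsets 23 of 23 class I and 11 of 12 class II genes rose. WT replicate 3 had the highest class II median among WT libraries, 0.82 above the WT mean, where the others lay between -0.29 and -0.24. Under library totals, with which 70.7% of the genes past the threshold rose, the class II list lost its call (Fisher's exact adjusted p = 0.0664, range over alternatives 2.4e-04 to 1), with 11 risen, 0 fallen and a median of 4.38.

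Complement and chemokine genes were also higher. On the complement list 17 of 18 listed genes rose (Fisher's exact adjusted p = 6.1e-04), among them C1qa (3.13 ± 0.10), C1qb (3.18 ± 0.14) and C1qc (2.91 ± 0.15), which form the recognition molecule C1q and are also on the macrophage and monocyte list, and C4b (2.67 ± 0.08). The exception was Cd59a, an inhibitor of the membrane attack complex, which fell by 0.99. On the list of chemokines and leukocyte adhesion genes, 20 of 23 listed members rose (Fisher's exact adjusted p = 0.00146). Ccl8 rose by 5.42 ± 0.40, Cxcl9, a ligand that draws activated T cells, by 5.63 ± 0.39, Ccl5 by 3.27 ± 0.23 and Ccl12 by 3.95 ± 0.20, while Ccl11, Ccl21a and Cxcl14 fell. With GC offsets 13 complement genes rose and none fell, and 18 chemokine list genes rose and 2 fell. Among genes above the median level the chemokine list did not pass (Fisher's exact adjusted p = 0.177, range over alternatives 2.0e-05 to 1). The complement call was lost under library totals, with which 70.7% of the genes past the threshold rose (Fisher's exact adjusted p = 0.0581, range over alternatives 1.8e-05 to 1), at 17 risen, 1 fallen and a median of 1.93, and the chemokine median of ARE-/- replicate 1 was 3.03, against 1.89 to 2.06 in the others.

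Markers of several immune cells were higher in ARE-/- hearts. Of 22 listed macrophage and monocyte markers, 21 rose (Fisher's exact adjusted p = 8.4e-05, median 2.54), with the Fc receptor Fcgr4 at 4.97 ± 0.32, and Cd163, a marker of resident macrophages, was the 1 that fell. Of 24 listed T cell and NK cell markers, 23 rose (Fisher's exact adjusted p = 3.4e-05, median 2.24), including the cytotoxic granule gene Nkg7 (3.50 ± 0.26), the interleukin receptor chain Il2rb (2.91 ± 0.31), Klrk1 (3.40 ± 0.41) and Lag3 (2.40 ± 0.30). With GC offsets 20 markers of each list rose and none fell. Dendritic cell markers did not pass the test, with 7 of 8 listed members risen (Fisher's exact adjusted p = 0.0934, 6 risen with GC offsets), but they did in 7 of 19 alternatives (range 0.0186 to 0.168), among them those without WT replicate 2, 3 or 4 (Fisher's exact adjusted p = 0.0282, 0.0417 and 0.0283). All 5 listed neutrophil markers fell (Fisher's exact adjusted p = 0.0366, 5 of 5 also with GC offsets), a call lost with TMM (Fisher's exact adjusted p = 0.0989, range over alternatives 0.00473 to 0.0989). Mmp9 fell from 104 ± 27.4 to 26.5 ± 9.24 normalised counts, whereas the granule genes Ngp (23.6 ± 13.9 to 0.613 ± 1.23), Camp, Elane and Mpo were low in both groups (SD, n = 4 each). Of the B cell and plasma cell list 3 genes were listed, Pax5 (-2.67 ± 0.56) and Ighg1 (-1.53 ± 0.62) fallen and Sdc1 (0.75 ± 0.20) risen, too few for a test, and 2 of the 3 fell with GC offsets.

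**Figure D1:**
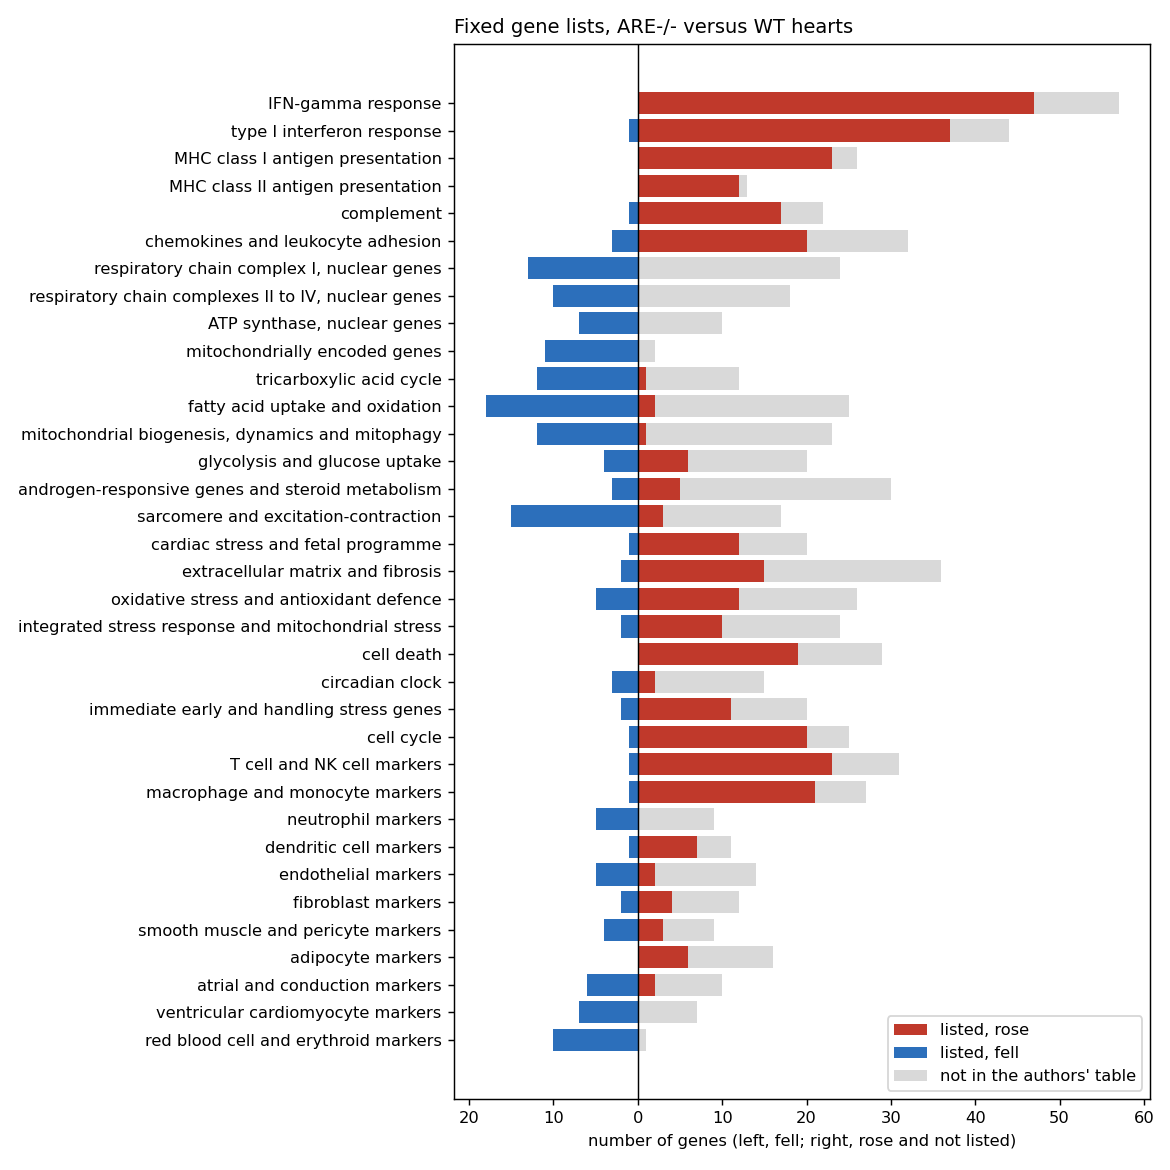
Number of genes of each fixed list with at least 5 listed members that rose (red) or fell (blue) in the authors' deposited table, or were not listed there (grey), with genes on the horizontal axis and lists on the vertical axis. All 47 listed IFN-γ response genes rose, and all 13 listed nuclear genes of complex I fell.

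Listed transcripts of the respiratory chain were lower in ARE-/- hearts, from both the nuclear and the mitochondrial genome. Of 37 nuclear genes of complex I, 13 were listed and all 13 fell (Fisher's exact adjusted p = 3.0e-04, median -0.68), including the core subunit Ndufs1 (-0.95 ± 0.06) and Ndufv3 (-1.06 ± 0.14). Of 28 nuclear genes of complexes II to IV, 10 were listed and all 10 fell (Fisher's exact adjusted p = 0.00146, median -0.65). Among them Uqcrc2 stood at -1.03 ± 0.03, Sdha at -1.05 ± 0.09 and the heart isoform Cox6a2 at -1.31 ± 0.27. Of 17 nuclear genes of ATP synthase, 7 were listed and all 7 fell (Fisher's exact adjusted p = 0.00914, median -0.76), Atp5o by -0.98 ± 0.10. All 11 listed genes of the mitochondrial genome fell (Fisher's exact adjusted p = 9.5e-04, median -0.77), with mt-Cytb at -1.12 ± 0.08 and mt-Nd4 at -1.14 ± 0.14. The 11 genes took 26.8% ± 2.64 of the reads in WT and 17.7% ± 2.00 in ARE-/- (SD, n = 4 each, exact permutation p = 0.0286). Values of mt-Co2 (-1.24 ± 0.15) are uncertain because nuclear copies can share its reads. Those of mt-Nd6 (-1.32 ± 0.20) are uncertain because it lies on the strand opposite to mt-Nd5 and the counter's use of strand is not given.

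The size of these falls moved with the GC trend. With GC offsets 5 of 13 complex I genes and 6 of 10 genes of complexes II to IV fell past the threshold. So did 3 of 7 of ATP synthase and 1 of 11 mitochondrially encoded genes. No listed gene of these 4 lists rose past it. In the same order 2, 3, 0 and 2 listed genes lay above 0, with list medians of -0.23, -0.42, -0.40 and -0.14. Ndufs1 stood at -0.23 and mt-Cytb at -0.52 in that refit, neither past the threshold of edgeR, while Ndufv3 stood at -1.52 and Cox6a2 at -1.72, both past it. The lowest median of the complex I list was that of ARE-/- replicate 1, -1.11, against -0.66 to -0.53 in the other ARE-/- libraries. ATP synthase had 4 fallen genes under library totals, too few for a test.

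Most listed fuel oxidation genes fell alongside, and members that were not listed have no known direction. Of 43 genes of fatty acid uptake and oxidation 20 were listed and 18 fell (Fisher's exact adjusted p = 5.4e-04, median -0.93). Acadm, the medium-chain acyl-CoA dehydrogenase, fell from 19362 ± 467 to 6115 ± 216 normalised counts (SD, n = 4 each), a log2 difference of -1.66 ± 0.03. Hadhb (-1.15 ± 0.06), Etfdh (-1.13 ± 0.05) and Eci2 (-1.08 ± 0.08) followed, and the exceptions that rose were the lipid droplet protein Plin2 and the nuclear receptor Ppard. Of 24 genes of the tricarboxylic acid cycle 13 were listed and 12 fell (Fisher's exact adjusted p = 0.00257, median -0.71). The fallen included Sucla2 (-0.85 ± 0.03), Idh3a (-0.93 ± 0.07) and Sdhd (-0.71 ± 0.07), and Pcx, which feeds the cycle from pyruvate, rose. Of 35 genes of mitochondrial biogenesis, dynamics and mitophagy 13 were listed and 12 fell (Fisher's exact adjusted p = 0.00257, median -0.60). Among the fallen were Opa1 (-0.66 ± 0.05), Ppargc1a (-0.74 ± 0.12), Tfam (-0.54 ± 0.05) and Dnm1l (-0.84 ± 0.17). With GC offsets 9 fatty acid genes fell and 1 rose, and 4 genes of the tricarboxylic acid cycle fell. The biogenesis list then had 1 risen and 1 fallen gene, with 8 of 13 above 0, Opa1 and Tfam among them (0.023 and 0.16), and a median of 0.053. The biogenesis list had 3 fallen genes under library totals, too few for a test.

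Lists of glycolytic and androgen-related genes did not pass the test in either direction. On the list of glycolysis and glucose uptake 6 of 10 listed genes rose (Fisher's exact adjusted p = 0.756). Within it Pfkfb1 fell by -2.79 ± 0.16 and Pdk1 by -0.71 ± 0.04, whereas Pfkfb3, a related activator of glycolysis, rose by 1.94 ± 0.17 and Pfkp by 1.25 ± 0.09. The glycolysis median was 0.17 in ARE-/- replicate 1, against 0.97 to 0.98 in the other ARE-/- libraries. The list of androgen-responsive genes and steroid metabolism had 8 of 33 genes listed, 5 risen and 3 fallen (Fisher's exact adjusted p = 0.7497). Igf1r (1.36 ± 0.37), Fkbp5 (0.66 ± 0.11) and Hsd11b1, which regenerates active glucocorticoid (0.54 ± 0.11), rose, and Amd1, of polyamine synthesis, fell by -1.20 ± 0.17. Groups overlapped for Igf1r. With GC offsets 4 genes of the androgen list rose and 1 fell, and 2 glycolytic genes moved each way.

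Most listed contractile genes were lower, and most listed genes of the cardiac stress list were higher. Of 32 sarcomere and excitation-contraction genes 18 were listed and 15 fell (Fisher's exact adjusted p = 0.00612, median -0.62). The fallen included the giant spring protein gene Ttn (-1.33 ± 0.08), Csrp3 (-0.99 ± 0.13), the troponin Tnnt2 (-1.28 ± 0.23) and the gap junction gene Gja1 (-0.63 ± 0.07). Des, Tcap and Hcn4 rose. All 7 listed of 14 ventricular cardiomyocyte markers fell (Fisher's exact adjusted p = 0.00914). They included Pln (-0.61 ± 0.07), Ckmt2 (-0.78 ± 0.13) and Myl2 (-0.89 ± 0.23). Atrial and conduction markers did not pass, with 6 of 8 fallen (Fisher's exact adjusted p = 0.197), although Myl4 (-0.77 ± 0.07) and Myl7 (-0.97 ± 0.11) were among the fallen. With GC offsets 6 sarcomere genes fell and 1 rose, 6 ventricular and 3 atrial markers fell, the sarcomere list no longer passed (Fisher's exact adjusted p = 0.0567, range over alternatives 5.7e-04 to 0.667, the highest with a log2 fold change of at least 1), and Gja1 and Pln stood at 0.073 and 0.058. For ventricular markers the median of ARE-/- replicate 1 was the lowest, -1.17, against -0.69 to -0.63 in the others.

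Of 21 cardiac stress and fetal genes 13 were listed and 12 rose (Fisher's exact adjusted p = 0.00651, median 1.504). RNA of whole hearts does not tell which cells carried these rises. Lgals3, which encodes the macrophage lectin galectin 3, rose by 3.73 ± 0.14, the stress cytokine Gdf15 by 3.75 ± 0.38, Rcan1, a target of calcineurin, by 1.14 ± 0.09 and the matrix protein gene Tnc by 3.23 ± 0.43. The interleukin 33 receptor gene Il1rl1 fell. Extracellular matrix genes leaned upward, 15 of 17 listed (Fisher's exact adjusted p = 0.00515, median 0.77), with Timp1 (2.68 ± 0.39), Tgfb1 (1.48 ± 0.29), Tgfbr2 (0.85 ± 0.13) and Tgfb3 (0.72 ± 0.04). With GC offsets 9 stress genes rose and none fell, 7 matrix genes rose and 1 fell, and the matrix list no longer passed (Fisher's exact adjusted p = 0.171, range over alternatives 0.00246 to 0.171). The matrix list passed in 11 of 19 tested alternatives, and those in which it did not included leaving out WT replicate 1, 2 or 4 or ARE-/- replicate 2, 3 or 4 (Fisher's exact adjusted p = 0.101, 0.105, 0.168, 0.0700, 0.107 and 0.107). Under library totals neither list passed (Fisher's exact adjusted p = 0.176 for stress genes, with a range over alternatives of 0.00162 to 1, and 0.128 for matrix genes), with 12 stress genes risen and 1 fallen (median 1.88), 14 matrix genes risen and 1 fallen (median 0.99), and 70.7% of all genes past the threshold risen.

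Cell death and cell cycle genes were higher. All 19 listed cell death genes rose (Fisher's exact adjusted p = 3.4e-05, median 1.59), with Casp1 (3.99 ± 0.45), Bak1 (1.75 ± 0.18) and the inflammasome adaptor Pycard (1.59 ± 0.16) beside Zbp1. Of 21 listed cell cycle genes 20 rose (Fisher's exact adjusted p = 1.3e-04, median 1.22), including the replication helicase genes Mcm5 (2.03 ± 0.14), Mcm2 (1.58 ± 0.19) and Mcm3 (1.16 ± 0.10), and Cenpf was the 1 that fell. With GC offsets 16 cell death genes rose and none fell, and 17 cell cycle genes rose and 1 fell. Among genes above the median level the cell cycle list did not pass (Fisher's exact adjusted p = 0.481, range over alternatives 1.8e-05 to 0.481). Immediate early genes passed narrowly, 11 of 13 risen (Fisher's exact adjusted p = 0.0362), with Junb at 1.62 ± 0.19, Zfp36 at 0.91 ± 0.17 and Nr4a1 fallen at -0.97 ± 0.20. They did not pass under library totals (Fisher's exact adjusted p = 0.423, range over alternatives 0.0337 to 0.534), at 11 risen, 2 fallen and a median of 0.98, and with GC offsets 3 rose and 1 fell. They passed in 5 of 19 tested alternatives, and those in which they did not included leaving out WT replicate 1, 2 or 4 or ARE-/- replicate 2, 3 or 4 (Fisher's exact adjusted p = 0.534, 0.353, 0.182, 0.361, 0.513 and 0.513). The integrated stress response list did not pass (10 of 12 risen, Fisher's exact adjusted p = 0.0543, 6 risen and 1 fallen with GC offsets). Nor did oxidative stress genes (12 of 17 risen, Fisher's exact adjusted p = 0.186, 9 risen and 3 fallen with GC offsets). Oxidative stress genes passed in 1 of 20 alternatives, at an authors' log2 fold change of at least 1 (Fisher's exact adjusted p = 0.0125). Circadian clock genes did not pass either (2 of 5 risen, Fisher's exact adjusted p = 0.7497, 1 risen and 1 fallen with GC offsets). Within these lists the mitochondrial folate enzyme Mthfd2 (1.81 ± 0.27), the oxidase subunit Cyba (1.84 ± 0.09), Xdh (2.13 ± 0.25) and Hmox1 (1.68 ± 0.22) rose. The mitochondrial chaperones Hspd1 (-0.86 ± 0.10) and Hspa9 (-0.82 ± 0.10) fell, as did the clock genes Nr1d2 (-0.997 ± 0.16), Ciart (-1.67 ± 0.30) and Arntl (-0.37 ± 0.06), the last at 0.050 with GC offsets.

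**Figure D2:**
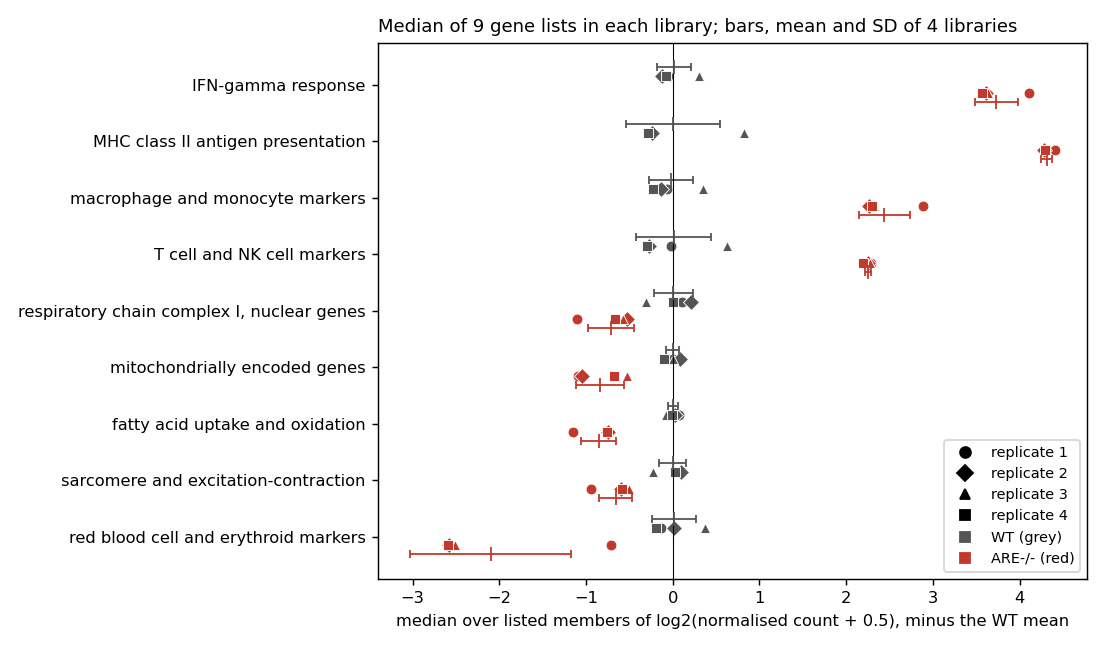
Median over listed members of log2(normalised count + 0.5), as a difference from the WT mean (horizontal axis, log2 units), for 9 gene lists in each library, with WT in grey, ARE-/- in red, marker shapes for replicate numbers and bars for the mean and SD of 4 libraries. ARE-/- replicate 1 stands at -0.71 for the erythroid list, where the other ARE-/- libraries stand at -2.59 to -2.51.

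Red-cell transcripts were lower in ARE-/- hearts. All 10 listed of 11 erythroid markers fell (Fisher's exact adjusted p = 0.00146, median -2.10), with the anion exchanger gene Slc4a1 at -2.04 ± 0.37 and Bpgm, an enzyme of red-cell glycolysis, at -1.71 ± 0.38 beside the globins, and 10 of 10 fell with GC offsets. The 4 listed haemoglobin genes took 4.74% ± 0.341 of the reads in WT and 1.45% ± 1.29 in ARE-/- (SD, n = 4 each, exact permutation p = 0.0286). Of these, ARE-/- replicate 1 held 3.39%, and the other ARE-/- libraries 0.756% to 0.841%.

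**Figure D3:**
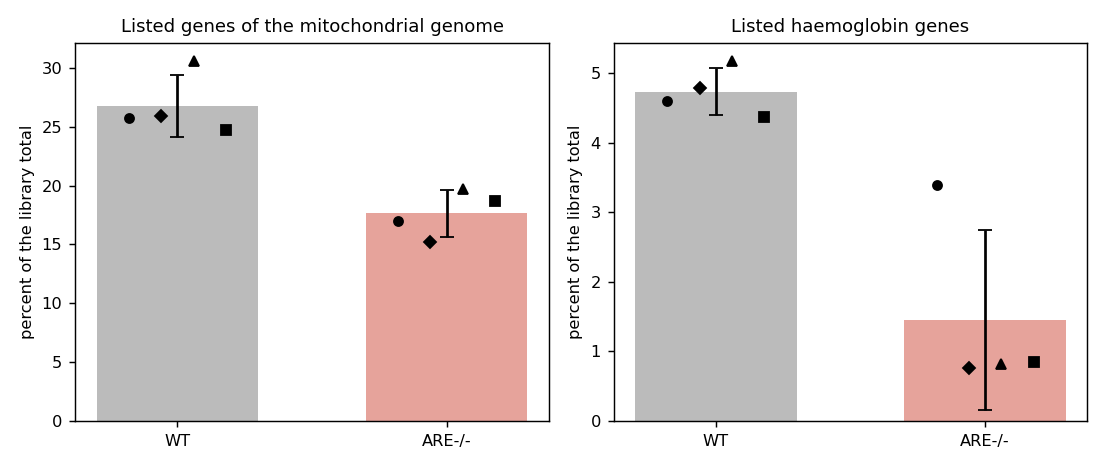
Share of each library's reads in the 11 listed genes of the mitochondrial genome (left) and the 4 listed haemoglobin genes (right), in percent of the library total, with points for libraries (marker shapes for replicate numbers, circle 1, diamond 2, triangle 3, square 4) and bars for the mean and SD of 4 libraries. Every ARE-/- library lies below every WT library in both panels.

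Endothelial, fibroblast and smooth muscle and pericyte markers did not pass the test as lists, and those of fat passed only narrowly. With so few listed members a lean could be missed. Endothelial markers had 5 of 7 listed members fallen (Fisher's exact adjusted p = 0.316), among them Flt1 (-0.71 ± 0.20), Egfl7 (-0.64 ± 0.18) and Prox1 (-0.50 ± 0.07), with Cldn5 risen (0.65 ± 0.13). Fibroblast markers split into 4 risen and 2 fallen (Fisher's exact adjusted p = 0.7497), Tcf21 (0.98 ± 0.17) and Col3a1 (0.77 ± 0.13) against Smoc2 (-1.06 ± 0.12) and Pi16 (-0.84 ± 0.19). Smooth muscle and pericyte markers split into 3 risen and 4 fallen (Fisher's exact adjusted p = 0.7497), with the pericyte genes Rgs5 (-1.51 ± 0.27), Kcnj8 (-0.84 ± 0.15) and Abcc9 (-0.99 ± 0.24) fallen and Cnn1 (1.45 ± 0.44) risen. All 6 listed adipocyte markers rose (Fisher's exact adjusted p = 0.0448), with Cidec at 2.14 ± 0.44, Cfd at 2.16 ± 0.50, Plin1 at 1.75 ± 0.59 and Adipoq at 1.504 ± 0.40, but WT replicate 3 stood 1.21 above the WT mean for this list, against -0.38 to -0.34 in the other WT libraries. The adipocyte list passed in 3 of 9 tested alternatives. Its call was lost among protein-coding genes (Fisher's exact adjusted p = 0.0522), above the median level (0.0652) and at a mean of at least 50 reads (0.116). It was also lost under library totals (Fisher's exact adjusted p = 0.409, range over alternatives 0.0417 to 0.409), at 5 risen, 0 fallen and a median of 1.66, and without ARE-/- replicate 1 (Fisher's exact adjusted p = 0.0854), and 2 of the 6 rose with GC offsets. Without WT replicate 1, 2 or 4 or ARE-/- replicate 2, 3 or 4, fewer than 5 adipocyte markers passed, too few for a test. The mesothelial keratin genes Krt18 (1.00 ± 0.30), Krt8 (0.76 ± 0.24) and Krt19 (0.71 ± 0.25) were listed as risen, too few for a test, and none passed with GC offsets. With GC offsets 1 endothelial, 2 fibroblast and 3 smooth muscle and pericyte markers fell, and 2 fibroblast markers rose. Of the markers of lung, thymus and liver (19 genes), of skeletal muscle (13) and the sex-linked genes (6), 0 were listed.

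Adjusted over the list alone, at least every listed member passed the threshold, in every list that had listed members. This follows largely from the selection of listed genes at an adjusted p under 0.05. Members that were not listed carry no p here. In the authors' deposited table the adjusted p of the genes named by the rule reached 0.042 for Arntl and 0.037 for Mpo (DESeq2), the weakest of them.

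The authors' deposited table of GO terms holds 2065 enriched terms, 1740 of them biological processes, and immune terms lead it. For biological processes its background held 20349 genes, more than the 19606 tested. Enrichment was therefore not set against the genes tested in heart alone. Positive regulation of immune response counted 220 listed genes of 477, 189 of them risen and 30 fallen, with an adjusted p of 8.5e-31 in the authors' deposited table. Next came regulation of leukocyte activation (198 genes, 162 risen) and T cell activation (200 genes, 167 risen), with adjusted p of 1.1e-22 and 2.4e-22 in the authors' deposited table. Members whose symbol had no match have no direction here, 8 of 62 in cellular respiration. At least 75% of the matched members had risen in 835 terms and had fallen in 54. Among the latter, cellular respiration had 43 fallen and 11 risen genes, the mitochondrial matrix 61 fallen and 13 risen, and the tricarboxylic acid cycle 12 fallen and 0 risen. Their adjusted p in the authors' deposited table were 2.4e-06, 0.00544 and 0.0402. Terms of sarcoplasmic reticulum calcium ion transport (13 of 15 fallen) and cardiac muscle cell contraction (17 of 20 fallen) were also on that side.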

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

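The tests of repeat libraries, of WT RNA in ARE-/- replicate 1, of scaling, of the cardiomyocyte share and of how much GC content sets the size of falls were chosen after the results were seen. Within each group of 4 libraries, the gap of the highest or lowest library to its neighbour was set against the group's range. Of 78 such groups 19 passed Dixon's 95% critical value, where chance gives about 1 in 20, and ARE-/- replicate 1 made 13 of them and WT replicate 3 made 5.

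WT replicate 3 stood above the other WT libraries in the list medians of IFN-γ response (gap over range 0.839), MHC class I (0.887), MHC class II (0.962), oxidative stress (0.889) and adipocyte markers (0.977). ARE-/- replicate 1 stood above its group in the haemoglobin read share (0.968) and in the medians of IFN-γ response (0.863), MHC class II (0.886), chemokines (0.849), cell death (0.8997), macrophage markers (0.907) and erythroid markers (0.961). It stood below its group in the medians of MHC class I (0.834), fatty acid oxidation (0.955), glycolysis (0.991), fibroblast markers (0.963), adipocyte markers (0.885) and ventricular markers (0.896). ARE-/- replicate 4 stood below its group in neutrophil markers (0.995), a list of low counts. Among the 149 named genes, ARE-/- replicate 1 stood apart in 39, WT replicate 3 in 16, ARE-/- replicate 2 in 2 and WT replicate 4 in 1.

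In each group 3 libraries lay close together and the fourth stood apart, with a biological coefficient of variation of 6.08% (WT) and 5.88% (ARE-/-) among the close libraries. WT RNA mixed into ARE-/- replicate 1 is argued against as the only source of its distance, because 52.5% of the 1275 genes that rose at least 2-fold were highest in that library and 34.4% lowest, where mixing would make it the lowest; mixing beside another difference stays open, since 41.7% of genes that fell at least 2-fold were highest there and 22.9% lowest. A GC bias may account for part of its distance. Its deviation from the other ARE-/- libraries had a Spearman correlation with transcript GC content of -0.639 across genes, against 0.0975 with length. Deviations of the other ARE-/- libraries, measured in the same way, had correlations with GC content of 0.45 to 0.64. Each deviation is relative to the rest of the group, so it cannot be told which libraries carry the bias. Repeat libraries of a single RNA or pool cannot be told apart from very similar mice, because the larger coefficient of variation of the close libraries, 0.0608, lies between the bounds set for each. Real differences between mice of one genotype stay open and were not tested.

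Erythroid transcripts fell in ARE-/- hearts, by a median of -2.10, and least in ARE-/- replicate 1. Scaling is argued against as the source, since the median stayed at -1.91 with library totals. In the edgeR refit with library totals the median was -1.58, with 6 of 10 genes fallen past the threshold and 10 below 0. Less blood left in the ARE-/- hearts is a possible explanation that cannot be told apart from fewer or less haemoglobin-rich red cells, because the 4 listed platelet and megakaryocyte markers, another part of blood, had a median of -0.75, between the bounds set for each. An effect of the genotype on red cells stays open and was not tested.

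Mitochondrial and contractile transcripts fell in ARE-/- hearts, 98 of 105 listed genes. Other listed genes matched on transcript length or GC content fell less often. The share fallen in the set was 93.3%. It stood at percentile 100 of 10000 draws matched on length (highest 62.9%) and of 10000 matched on GC content (highest 72.4%). The lists that make up the set all leaned down in these same libraries, so a high percentile was likely in advance. Length and GC content are therefore not excluded as a source of the direction. A lower share of cardiomyocyte RNA alone would raise all other cell types alike. Macrophage medians (2.26 to 2.88) lay at least 2.75 above those of smooth muscle and pericytes (-0.76 to -0.49) in every ARE-/- library. This cannot decide the question, since the 7 listed smooth muscle and pericyte markers split into 3 risen and 4 fallen. Their median was -0.27 with GC offsets. A lower share of cardiomyocyte RNA and an influx of immune cells both stay open. GC content may set much of the size of the falls. GC offsets took away 69.1% of the set's median, from -0.71 (quartiles -0.93 and -0.57) to -0.22 (-0.90 and 0.03). Members below 0 numbered 98 before and 76 after, and fallen genes 88 before and 35 after, as folds shrank or turned. The set's median GC content was 47.2%, against 50.4% of listed genes. ARE-/- replicate 1 carried less of the GC trend than the other ARE-/- libraries (correlation of its deviation with GC content -0.639). Its median was nonetheless the lowest for complex I (-1.11, others -0.66 to -0.53) and fatty acid oxidation (-1.15, others -0.76 to -0.74). For biogenesis it was the highest (-0.43, others -0.61 to -0.50). As medians of 1 library they do not settle the share of GC content. The authors' size factors are argued against as the whole source, since the median was -0.52 (quartiles -0.74 and -0.38) in the refit with library totals, 98 of 105 genes lay below 0 there and 65 of the 85 fallen genes with separate groups had them, whereas part of the size of the falls moves with scaling and an effect of the genotype itself stays open and untested.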

How the results depend on the processing

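Scaling by library totals, GC offsets, leaving out both libraries that stood apart and summing the close libraries were chosen after seeing the data. Ifng was higher in ARE-/- in every refit run, with log2 differences of 4.54 to 6.72. The 2368 values of named genes under the alternatives held direction and call in 2162, lost the call in 201 and changed direction in 5; the 619 values of single lists did so in 562, 45 and 4, and 8 gained the call. Except where fewer genes or samples entered, the cause was not tested.

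Changed genes numbered 3132 at an adjusted p under 0.01, 2321 with an authors' log2 fold change of at least 1, 2410 above the median level, 2444 with GC offsets and 297 with the close libraries summed. At 297 the design compares 2 replicates with 2, and 2321 genes had an unadjusted p under 0.05. Leaving out a library gave 2765 to 4527 genes: 2765, 2801, 3687 and 2767 without WT replicates 1 to 4, and 4527, 2931, 2989 and 2921 without ARE-/- replicates 1 to 4. Over the 35 splits of the 8 libraries into 4 and 4, the edgeR refit called 4292 genes on the real split, the 1 split with as many, and at most 0 on the others. Since the genes had been selected on the real split, this cannot say whether chance is excluded.

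The share that rose, 52.1%, was 56.4% at an adjusted p under 0.01, 53.8% at the fold minimum, 59.1% at a mean of at least 50 reads, 57.6% above the median level, 55.0% among protein-coding genes, 42.1% with TMM, 70.7% with library totals, 57.4% with GC offsets, 91.9% with the close libraries summed, and 52.0% to 56.7% without each library. Lists past the threshold numbered 25, against 15 at the fold minimum, 17 with GC offsets, 17 with library totals and 18 to 26 without each library, not always from among the 25. With the close libraries summed 0 passed by Fisher's exact test, adjusted or unadjusted, 9 lists being large enough to test. With 91.9% of called genes risen, this test could hardly call a rising list. IFN-γ response still had 39 risen, 0 fallen and a median of 3.78, and MHC class I 19, 0 and 2.97. No listed gene was called for complex I, complexes II to IV, ATP synthase, the mitochondrial genome, the tricarboxylic acid cycle, biogenesis, sarcomere or erythroid genes. Medians of these lists stayed between -1.45 and -0.55. Of fatty acid genes 1 of 20 fell (median -0.97), and of cell death genes 2 of 19 rose (median 1.74). GO terms numbered 1345 at an adjusted p under 0.01.

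Directions turned in lists that had not passed: the median of circadian clock genes was 0.050 with GC offsets and, relative to all other genes, glycolysis leaned down with library totals (60% rose), without WT replicate 4 (55.6%) and without ARE-/- replicate 3 (55.6%), and fibroblast markers with library totals (66.7%). With GC offsets the biogenesis list, which had passed, also turned (median 0.053, 8 of 13 above 0, too few past the threshold to test). In that refit Opa1 (0.023), Tfam (0.16), Gja1 (0.073), Arntl (0.050) and Pln (0.058) stood above 0, none past the threshold.

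The replicate numbers are not said to pair the libraries. Correlations of deviations between same-numbered libraries were 0.02, 0.06, -0.14 and 0.20. Between other libraries of the 2 groups they ran from -0.22 to 0.18, so pairing is neither shown nor excluded. With the replicate number as a block 3473 genes passed, 53.6% of them risen, and 22 lists; Ifng stood at 5.30. The planned set tests on all genes (camera), the fit without a filter on low counts and the change of pseudocount were not run, since the gene table is a selection. Without 1 library, 13 named genes lost the call at least once (11 each without WT replicate 1, 2 or 4, 2 without WT replicate 3, and 1, 7, 7 and 6 without ARE-/- replicates 1 to 4; edgeR adjusted p 0.0501 to 0.168): Adipoq, Arntl, Dbp, Egfl7, Flt1, Hsd11b1, Ighg1, Krt8, Krt18, Krt19, Mpo, Plin1 and Sdc1. Without WT replicate 1, 2 or 4, complexes II to IV had 4 fallen genes, too few to test, as did ventricular markers without WT replicate 1 or 2, and ATP synthase and neutrophil markers without any of these or ARE-/- replicates 2 to 4. Low counts limit the granule genes of neutrophils and Ifng in WT.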

Other observations

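The 6 gene lists of the first paragraphs here were drawn up after the data were seen, so their tests describe a pattern found in the same libraries, and their GC-offset counts were added later still. Enzymes that break down branched-chain amino acids were lower in ARE-/- hearts. All 11 listed of 21 fell (Fisher's exact adjusted p = 6.0e-04 over 6 lists, median log2 difference -0.87), led by Dbt, a subunit of the branched-chain ketoacid dehydrogenase (-1.65 ± 0.16 SE), and Ppm1k, the phosphatase that activates it (-1.23 ± 0.08), and 4 fell with GC offsets. Transcripts of mitochondrial and of cytosolic ribosomal proteins leaned opposite ways. Of 19 listed mitochondrial ribosomal genes of 78, 17 fell (Fisher's exact adjusted p = 6.0e-04, median -0.57), Mrps9 by -0.88 ± 0.10, and of 16 listed cytosolic ribosomal genes of 89, 15 rose (Fisher's exact adjusted p = 8.9e-04, median 0.53), with Rps29 fallen (-0.88 ± 0.33). With GC offsets 7 mitochondrial ribosomal genes fell and 1 rose (median -0.12, 6 of 19 above 0), and 8 cytosolic ones rose and 1 fell. Cytosolic ribosomal genes have many processed pseudogenes, so their counts are uncertain.

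Genes of actin remodelling rose throughout, 22 of 22 listed (Fisher's exact adjusted p = 3.9e-06, median 1.25), from Cotl1 (2.59 ± 0.17) and Coro1a (2.18 ± 0.27), both abundant in leukocytes, to the widely expressed Actb (0.86 ± 0.07) and Arpc4 (1.46 ± 0.09), and 18 rose with GC offsets. Nuclear receptor genes were mixed, 12 of 17 listed fallen (Fisher's exact adjusted p = 0.0865), among them Thrb (-0.81 ± 0.04) and Rora (-0.94 ± 0.22), with Nr1h3 (0.52 ± 0.13) risen, and with GC offsets 3 fell and 1 rose. The 4 listed platelet and megakaryocyte markers all fell, Pf4 by -0.58 ± 0.14 (Fisher's exact adjusted p = 0.0630, not past the threshold as a list), and 3 fell with GC offsets.

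A hypothesis tested was that sequence linked to the targeted locus could place changed genes near Ifng. Of 159 protein-coding genes within 10 Mb of Ifng, 34 were listed (21.4%), against 20.1% of 21791 elsewhere, an odds ratio of 1.08 with a 95% interval of 0.716 to 1.59 (Fisher's exact p = 0.691). No excess was detectable, and the interval leaves a modest one open.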
